A study of Homo sapiens with 6 samples.

How the data were processed

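RNA from 6 libraries of the human line Het1A, 3 control and 3 bile acid, was sequenced with paired-end reads of 150 bp on an Illumina instrument, per the labels' protocols. Cells were kept in 1% serum from 48 h before the first exposure. HISAT2 2.0.5, featureCounts, DESeq2 and GRCh38 are named in the submitters' processing notes, without their roles. The annotation is not given in the sources used here, and the gene coordinates and lengths in the deposited table equal those of GENCODE release 29, which is Ensembl release 94, for 100% of genes. Whether reads were counted by strand is not given in the sources used here, so antisense and overlapping genes cannot be told from their partners.

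The deposited count table holds whole-number read counts per gene for 58735 genes, of which 27713 are 0 in every library. The deposited FPKM values are counts per kilobase of gene and per M fragments as the authors computed them, and the deposited group means equal the means of the single libraries within 2.26e-07. The authors also deposited normalized counts, a signal that is never negative and that equals whole reads divided by 1 size factor per library, with 100% of values whole within 0.001. These recovered reads, 31530 genes in all, exceed the count table in total by 3.84% to 4.20% per library, and 44.1% to 53.6% of genes are equal, so they come from another counting. Per the file headers, the deposited comparison gives for each gene a mean signal, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value in the layout of DESeq2. DESeq2 on the recovered reads gave the same log2 fold changes within 3.76e-05 and the same 19 calls. The deposited gene set table gives, per the file headers, other values such as term size and rank, an enrichment score with its normalized score, and p-values for each Gene Ontology term. The tool behind it is not given in the sources used here, and 2 further value columns were not used here.

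Groups were taken from the labels. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM factors, the filter filterByExpr and a Benjamini-Hochberg adjusted p under 0.05, comparing 3 bile acid with 3 control libraries without covariates. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. Per gene, CPM are TMM-scaled. The correlation-adjusted set test camera of limma 3.58.1 was run on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over 34 gene lists, and list medians and means are those of the log2 CPM fold changes. Of 761 distinct symbols in the lists 760 were found in the table, older symbols included. Counts of list members are given over all genes and adjusted over the list alone. The lists cover NF-κB targets, interferon, endoplasmic reticulum chaperones, ATF4 targets, NRF2 targets, cholesterol, fatty acids, p53 targets, DNA repair, DNA replication, mitosis, basal and differentiated squamous, columnar and mesenchymal markers, junctions, matrix proteases, bile acid handling, pH regulation, hypoxia and glycolysis, nuclear and mitochondrial genes of oxidative phosphorylation, heat shock, immediate-early genes, TGF-β and YAP targets, developmental signals, apoptosis, autophagy, histones, ribosomal proteins, and markers of fibroblasts, leukocytes, endothelium and columnar cancer lines. Length and GC trends were removed per library with lowess of span 0.3, and length trends were described over genes with a mean of at least 5 CPM. Overlap of exons was found with bedtools 2.31.1.

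The lists, the tests, the alternative settings and the rule for named genes were chosen before the data were examined. The rule took the 6 largest increases and 6 largest decreases among called protein-coding genes, up to 3 called members per list, and 17 fixed genes, namely CXCL8, IL6, PTGS2, HMOX1, NQO1, DDIT3, CDKN1A, MKI67, CDX2, KRT5, TP63, KRT8, CDH1, VIM, NR1H4, GPBAR1 and VDR. Since edgeR called 0 genes, the rule named the fixed 17 alone, and every other gene in the text was chosen after its values were seen. These are genes called in the deposited table or by DESeq2, list members with the smallest p in a called list or passing over their list alone with all libraries or without control 2, the metallothioneins, and the 15 higher and 3 lower protein-coding genes with the smallest DESeq2 adjusted p without control 2, leaving out genes named after a clone. Values of some single genes are not reported here.

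The alternative settings were DESeq2 1.42.0 and limma-voom, RLE, upper-quartile and library-size scaling, no filter or 1 CPM in at least 3 libraries, protein-coding genes alone, no mitochondrial genes, a replicate block, removal of the length and GC trend with and without that block, limma on log2(FPKM + 1) with and without a minimum mean of 0.5 and on log2(FPKM + 0.1) with it, a minimum fold of 1.2, and each library left out in turn. For lists they were an estimated correlation, the rotation test fry, the block, RLE factors, the CPM filter, genes of 1 list alone and each library left out. Added after control 2 was seen to stand apart were DESeq2 without control 2, limma-voom with quality weights, edgeR and DESeq2 on the recovered reads, camera with the length and GC trend removed, and camera with an estimated correlation without control 2. Scaling moved the median log2 fold change of all genes between −0.03 and 0.01.

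The steps were tested on simulated counts drawn from the means and sizes of these libraries, with 200 genes changed. For 3 against 3 libraries and 17743 genes, edgeR recovered 5% of 2-fold and 72% of 4-fold changes with 6 false calls, DESeq2 36% and 94% with 56 false calls, and limma-voom 5% and 78% with 6 false calls. Without control 2, with 18274 genes, edgeR recovered 81% and 100% with 20 false calls and DESeq2 91% and 100% with 36 false calls. All libraries of a simulation shared the same spread per gene, so a library that stands apart was not simulated. A shift of 0.5 given to the cholesterol list was called by camera with an adjusted p of 4.5e-08 and no other list was called. Each gene was drawn independently there, so this says nothing on false list calls where members vary together. A length slope of −1 was recovered as −0.988 over 17513 genes. No libraries of a group were duplicates, since the chi-square per gene between any pair was at least 17.0.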

Results

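RNA was sequenced from Het1A cells, a line made from normal human oesophageal epithelium by immortalisation with SV40 large T antigen, to ask which genes respond to repeated short contact with acid and bile acids. In the 3 bile acid libraries the cells had been bathed for 10 min a day on 5 days in medium at pH 4.0 with 100 µM of a mix of glycocholic, taurocholic, glycodeoxycholic, glycochenodeoxycholic and deoxycholic acid. In the 3 control libraries they had received 0.1% DMSO, the solvent. RNA was taken 24 h after the last exposure from cells kept in 1% serum. The labels do not say that the control medium was acidified, so the values compare acid and bile acids together with the solvent. The labels call the libraries biological replicates 1 to 3 of each group without saying how the cultures were separated. The p-values of single genes therefore measure the spread between these libraries. Camera with the preset correlation compares list members with other genes and treats the members as nearly independent. Its p-values do not measure that spread. Total counts were 26218597, 21006677 and 21981806 in control libraries 1 to 3 and 27789590, 27008714 and 28497721 in bile acid libraries 1 to 3. At these depths a gene with 3 counts, the floor used here, lay at 0.105 to 0.143 CPM, a count scaled to a common library total, a limit that covers counting error only.

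Genes of cholesterol synthesis and uptake and immediate-early genes, which cells switch on within minutes of a stimulus, rose in the bile acid libraries. The median log2 fold change was 0.80 over 23 tested cholesterol genes, of which 21 had a positive value (camera, adjusted p = 6.4e-12). It was 1.40 over 25 tested immediate-early and MAPK feedback genes, all with a positive value (camera, adjusted p = 2.3e-15). Target genes of TGF-β and YAP rose by a median of 0.58 over 25 genes (camera, adjusted p = 3.5e-09), and cytosolic heat shock genes by 0.44 over 19 genes (camera, adjusted p = 3.0e-06). With an estimated correlation between genes, each of these 4 lists had an adjusted p = 0.411, and that adjusted p is the lowest that any of the 34 lists reached. With the preset correlation 15 of the 34 lists were called, 14 higher and 1 lower.

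No single gene was called among 17743 tested with edgeR, where the lowest adjusted p was 0.911 and 588 genes had an unadjusted p under 0.05, against 887 that chance alone gives. DESeq2 called 19 genes, all higher in the bile acid libraries, and limma-voom 0, with 528 genes under an unadjusted p of 0.05. On simulated counts of 3 against 3 libraries with 200 changed genes, edgeR made 6 false calls, limma-voom 6 and DESeq2 56. Of the 2-fold changes given there, edgeR recovered 5%, limma-voom 5% and DESeq2 36%. All simulated libraries shared the same spread per gene, so a library that stands apart was not simulated. The simulation therefore cannot tell how many of the DESeq2 calls here are false, or whether edgeR missed changed genes. The DESeq2 calls included FOS, EGR1, JUNB, DUSP1, ZFP36, MYC, CTGF, HMGCS1, INSIG1, FDFT1, HSPA6, DKK1, TMEM156, TFPI2, TM4SF1, CUL4B and IKBKGP1, of which the last is a pseudogene with a near-identical copy and is uncertain. In 938 genes every bile acid library lay above every control library and in 866 every one lay below, together 10.2% of the genes tested, where chance gives 10%. The edgeR count rose to 1 gene and the DESeq2 count to 158 when control library 2 was left out.

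Control library 2 stood apart from the other 5 libraries. The first principal component held 73.1% of the variance of log2 CPM and placed control 2 at 145 and the others between −44.0 and −6.89. Its log2 CPM correlated across genes with those of the other libraries at 0.958 to 0.975, while all pairs among the other libraries lay between 0.991 and 0.996 (Pearson, genes not being independent replicates). Control 2 had 19101 genes with at least 1 count, against 24174 to 25337 in the others and 24218 in control 3 thinned to the same total. Of antisense and lincRNA genes 2424 were detected in control 2 and 4206 to 4567 in the others, and of protein-coding genes 14498 and 15970 to 16314. The log2 difference of control 2 from the mean of controls 1 and 3 had an SD of 0.961 over 12077 genes, against 0.303 to 0.401 in the bile acid libraries. That difference fell with the exonic length of the gene, with a Spearman rho of −0.501 across genes, and bile acid library 2 showed a smaller trend of the same sign with a rho of −0.474. Genes shorter than 3350 bp had a median difference of 0.32 in control 2 and those longer than 7635 bp one of −0.93, while the medians in bile acid library 2 were 0.12 and −0.25. In control 2 the SD was 0.893 over 7362 genes with a share under 0.02 of their exonic length overlapped by another gene on either strand and 1.41 over 996 genes with a share of at least 0.2. The 20 most abundant genes took 7.90% of its counts and 5.03% to 6.12% of the counts of the others.

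**Figure D1:**
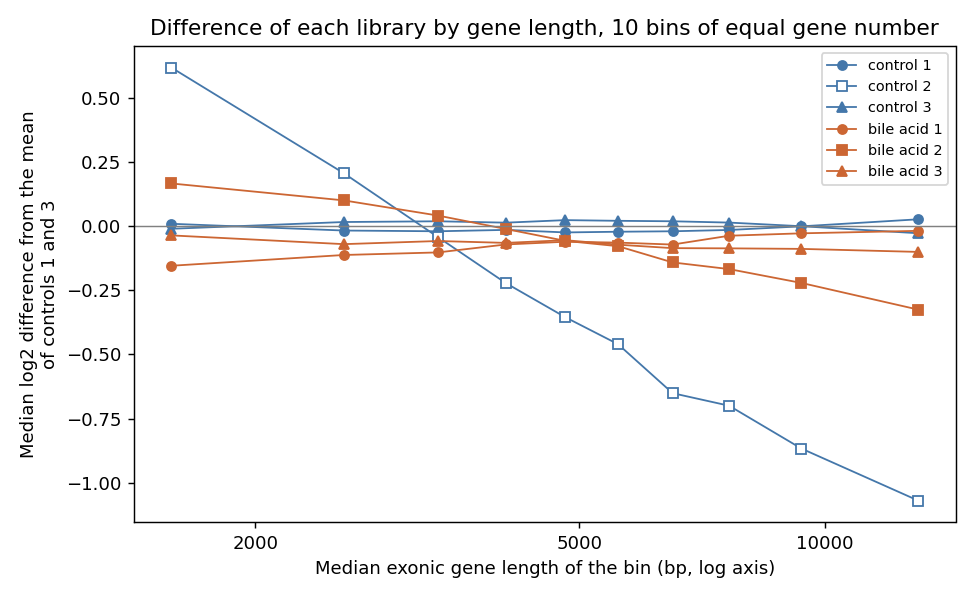
Median log2 difference of each library from the mean of control libraries 1 and 3 (vertical axis) against the median exonic length in bp (horizontal log axis) of 10 bins of equal gene number, with 1 line per library. Control 2 (open squares) runs from 0.62 in the shortest bin to −1.07 in the longest, and bile acid library 2 from 0.17 to −0.33.

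Among cholesterol genes, HMGCS1, which makes the HMG-CoA that feeds the mevalonate pathway (chromosome 5, 43289395 to 43313512, minus strand, GRCh38), measured 184 ± 61.3 CPM in bile acid libraries and 52.96 ± 13.2 CPM in control libraries (mean ± SD, n = 3), a log2 fold change of 1.80 (SE 0.32). INSIG1, which holds the sterol sensor SCAP in the endoplasmic reticulum (chromosome 7, 155297776 to 155310235, plus strand), measured 714 ± 163 CPM against 294.5 ± 30.1 CPM, a log2 fold change of 1.28 (SE 0.23). FDFT1, which makes squalene, measured 253 ± 65.9 CPM against 114 ± 10.5 CPM. All 3 bile acid libraries lay above all 3 control libraries for each of these 3 genes. Each had an adjusted p of 0.911 in edgeR over all genes, while all 3 were among the DESeq2 calls. Adjusted over the list alone, 10 of the 23 members rose in edgeR, among them these 3 and SQLE, IDI1, MSMO1, LSS and DHCR7, and over all genes tested 0 did. The list median relative to the gene means was −0.405, −0.44 and −0.45 in control libraries 1 to 3 and 0.11, 0.24 and 0.74 in bile acid libraries 1 to 3, so that control 2 lay beside the other controls on this list. Without control 2 the median was 0.72, with 20 members called in edgeR adjusted over the list alone and 10 in DESeq2 over all genes. Over the 14 alternatives tried for this list the adjusted p ranged from 9.3e-16 to 0.459.

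Genes of fatty acid synthesis and oxidation also rose, by a median log2 fold change of 0.38 over 21 tested members, 19 of them positive (camera, adjusted p = 4.5e-05, and adjusted p = 0.411 with an estimated correlation). FASN, the fatty acid synthase, measured 718 ± 239 CPM against 311 ± 169 CPM, ACLY, which supplies cytosolic acetyl-CoA, 479 ± 74.0 CPM against 300.4 ± 51.5 CPM, and ELOVL6, a fatty acid elongase, 42.8 ± 9.29 CPM against 24.7 ± 3.74 CPM (mean ± SD, n = 3). In edgeR 0 members passed adjusted over the list alone. Without control 2, whose list median was −0.55 against −0.09 and −0.10 in controls 1 and 3, the list median fell to 0.25 and 4 members, FASN, ELOVL6, ACLY and FADS2, passed over the list alone.

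**Figure D2:**
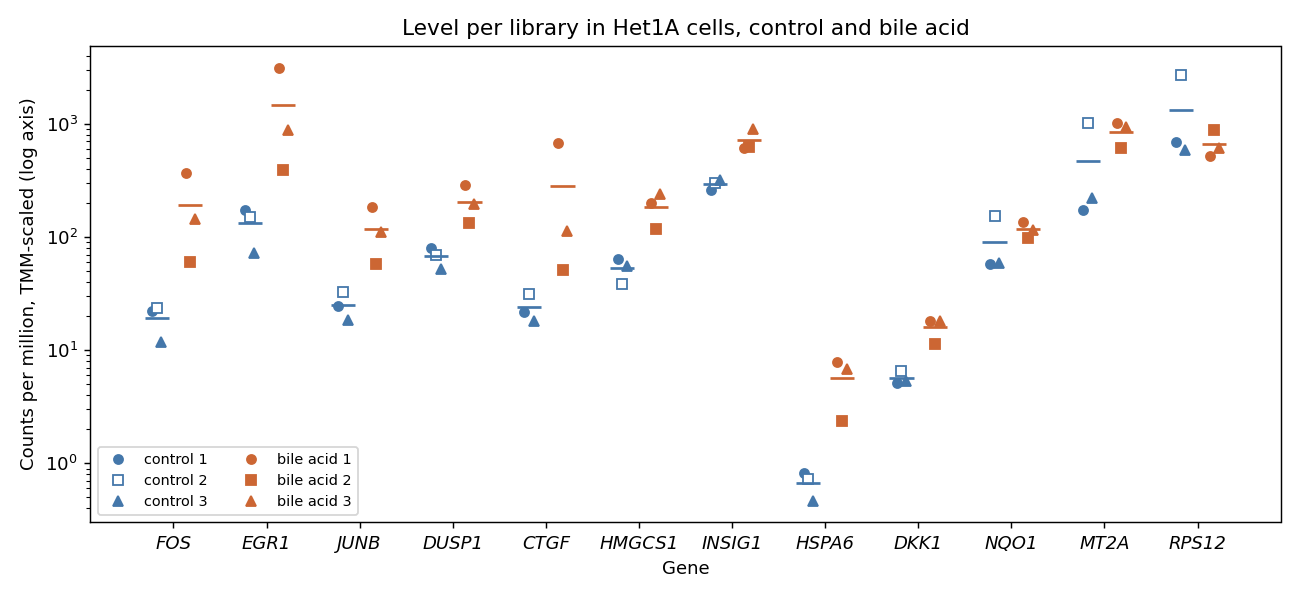
TMM-scaled CPM (vertical log axis) of 12 genes in each of the 3 control libraries (blue) and 3 bile acid libraries (orange), with symbols for library number, an open square for control 2 and a bar at the group mean. For HMGCS1 the control libraries have a mean of 52.96 CPM and the bile acid libraries one of 184 CPM, while for RPS12 and MT2A control 2 lies far above controls 1 and 3.

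Among immediate-early genes, FOS, a subunit of the transcription factor AP-1 (chromosome 14, 75278774 to 75282230, plus strand), measured 190 ± 158 CPM in bile acid libraries against 19.1 ± 6.37 CPM in control libraries, a log2 fold change of 3.32 (SE 0.66, n = 3). The zinc-finger factor EGR1 measured 1467 ± 1470 CPM against 132 ± 53 CPM, and JUNB, another AP-1 subunit, 117.5 ± 64.0 CPM against 25.2 ± 7.13 CPM. DUSP1, a phosphatase that switches MAP kinases off, measured 205.5 ± 78.7 CPM against 67.3 ± 14.3 CPM, and the growth regulator MYC 86.1 ± 24.7 CPM against 34.0 ± 7.43 CPM. Each of these genes was higher in 3 of 3 bile acid libraries than in every control. Adjusted over the list alone, 15 of the 25 tested members rose in edgeR and over all genes tested 0 did, while DESeq2 called FOS, EGR1, JUNB, DUSP1 and MYC. Bile acid library 1 stood apart on this list, with a median of 1.73 relative to the gene means against −0.02 and 0.40 in bile acid libraries 2 and 3 and −0.49, −0.78 and −0.66 in the control libraries. Without it the list median fell to 0.89 and the log2 fold change of EGR1 to 2.26, and the list call was kept (camera, adjusted p = 5.6e-14). The adjusted p of the list ranged from 4.2e-20 to 0.535 over its 14 alternatives.

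Target genes of TGF-β and YAP included CTGF, also named CCN2, a matrix-associated signalling protein, at 282 ± 347 CPM in bile acid libraries against 23.9 ± 6.94 CPM in control libraries. CYR61, its relative CCN1, measured 390 ± 395 CPM against 76.6 ± 16.8 CPM, with 842 CPM in bile acid library 1, and its log2 fold change of 2.35 fell to 1.10 without that library. The log2 fold change of CTGF was 3.56 in edgeR (SE 0.93) and fell to 1.79 without bile acid library 1. In that library CTGF stood at 681 CPM, against 51.1 CPM and 113.5 CPM in libraries 2 and 3. Its adjusted p was 0.0104 in DESeq2 and ranged from 0.0104 to 1 over all its alternatives. Of the 25 tested members 24 had a positive value and 0 passed in edgeR adjusted over the list alone. Control 2 had the lowest median of this list, −0.78, against −0.14 and −0.25 in controls 1 and 3, and without it 8 members passed over the list alone, among them ID1 and SMAD7.

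Target genes of NF-κB and cytokines rose by a median log2 fold change of 0.70 over 16 tested members, 15 of them positive (camera, adjusted p = 1.6e-05, and adjusted p = 0.411 with an estimated correlation). Without bile acid library 1 the median fell to 0.42. IL6, a cytokine, measured 1.44 ± 1.73 CPM against 0.335 ± 0.151 CPM, and PTGS2, the inducible cyclooxygenase, 4.00 ± 5.35 CPM against 0.986 ± 0.855 CPM, values that did not exceed the spread between libraries (edgeR, adjusted p = 0.911). In bile acid library 1 IL6 stood at 3.42 CPM and PTGS2 at 10.2 CPM, and without that library the log2 fold change of IL6 went from 2.11 to 0.44 and that of PTGS2 turned from 1.98 to −0.12. CXCL8, a neutrophil attractant, had 8, 0 and 5 counts in the control libraries and 28, 5 and 10 in the bile acid libraries, too few to be tested. Genes of the BCL2 family, caspases and death receptors rose by a median of 0.16 over 24 members (camera, adjusted p = 0.0313, and adjusted p = 0.581 with an estimated correlation), with MCL1, a survival factor, at 352 ± 252 CPM against 134 ± 13.6 CPM. MCL1 stood at 639 CPM in bile acid library 1, and its log2 fold change of 1.39 was 0.64 without it. The call of this list was lost without control 1 (camera, adjusted p = 0.453), control 3 (0.282) or bile acid library 1 (0.103). The call was also lost with the replicate block (0.121) and with the length and GC trend removed (0.0847), within a range of 0.000153 to 0.581 over the alternatives of this list. Its median was 0.246 without control 2 and 0.25 without bile acid library 2. In edgeR 0 members of either list passed adjusted over the list alone with all libraries, and without control 2 the NF-κB members IER3 and NFKBIA did.

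Cytosolic heat shock genes rose together, with 16 of the 19 tested members positive. HSPA6, an inducible HSP70 almost silent in unstressed cells, measured 5.655 ± 2.89 CPM against 0.674 ± 0.185 CPM (n = 3), a log2 fold change of 3.06 (SE 0.54). It was the only member that passed in edgeR adjusted over the list alone, with 0 passing over all genes, and the only one called by DESeq2. DNAJB1, a co-chaperone of HSP70, measured 202.5 ± 47.1 CPM against 117 ± 20.6 CPM, and the constitutive chaperone HSPA8 1722 ± 163 CPM against 1120 ± 330 CPM. The list median lay at 0.05 in control 2, against −0.59 and −0.36 in controls 1 and 3 and 0.14 to 0.33 in the bile acid libraries. Without control 2, 15 members passed in edgeR adjusted over the list alone and 8 in DESeq2 over all genes, HSPA1A and HSPA1B among them, which share nearly all of their sequence and are uncertain as single genes. The adjusted p of the list ranged from 3.0e-12 to 0.459 over its alternatives.

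Target genes of NRF2, the antioxidant regulator, rose by a median log2 fold change of 0.27 over 21 tested members, 15 of them positive (camera, adjusted p = 0.00514, and adjusted p = 0.411 with an estimated correlation). TXNRD1, a thioredoxin reductase, measured 150.4 ± 46.5 CPM against 70.2 ± 25.9 CPM. NQO1, a quinone reductase, measured 117 ± 18.4 CPM against 90.2 ± 55.6 CPM, with control 2 at 154 CPM, and HMOX1, the inducible haem oxygenase, 15.2 ± 6.88 CPM against 12.5 ± 4.72 CPM. HMOX1 had a log2 fold change of 0.29, which turned to −0.14 without bile acid library 1. The list median was 0.25 in control 2, against −0.25 and −0.30 in controls 1 and 3. The call was lost without control 1 (camera, adjusted p = 0.294) or control 3 (0.0982, with a median of 0.14), and the median reached 0.42 without bile acid library 2. Without control 2 the adjusted p was 2.2e-07, the lowest of the 14 alternatives, which reached 0.411, and 9 members passed in edgeR adjusted over the list alone where 0 did with all libraries. NQO1 then had a log2 fold change of 1.02 (SE 0.16).

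Genes of other stress pathways did not pass. ATF4 targets of the integrated stress response had a median of −0.22 over 21 members (camera, adjusted p = 0.0536). They fell without control 1 (−0.27, adjusted p = 0.0203) or bile acid library 2 (−0.41, adjusted p = 0.00142). They also fell with the replicate block (−0.22, adjusted p = 0.00791) or the filter of 1 CPM in 3 libraries (−0.24, adjusted p = 0.0464), within a range of 0.00142 to 0.77 over the alternatives. Without bile acid library 1 the median was −0.14 (adjusted p = 0.332). DDIT3, a stress-induced transcription factor of that list, measured 38.5 ± 18.3 CPM against 84.0 ± 77.6 CPM, with 173 CPM in control 2, and its log2 fold change of −1.12 was −0.02 without that library. Chaperones of the endoplasmic reticulum had a median of 0.16 over 19 members (camera, adjusted p = 0.112) and rose without control 2 (0.19, adjusted p = 0.00138) or bile acid library 3 (0.23, adjusted p = 0.00705). Targets of p53 had a median of 0.16 over 20 members (camera, adjusted p = 0.122) and rose without control 2 (0.17, adjusted p = 0.0128) or bile acid library 3 (0.16, adjusted p = 0.00937). In the latter list CDKN1A, the p21 cell cycle inhibitor, measured 120 ± 55.8 CPM against 72.85 ± 4.39 CPM and did not pass in edgeR (adjusted p = 0.911), and its log2 fold change of 0.725 was 0.28 without bile acid library 1. The highest adjusted p over the alternatives was 0.627 for the chaperone list and 0.748 for the p53 list. The chaperone median was 0.06 without bile acid library 1, and the p53 median 0.07 without that library and 0.30 without control 3. DNA repair genes had a median of 0.14 over 21 members (camera, adjusted p = 0.349), which was −0.05 without control 2 and 0.08 without bile acid library 1. Autophagy and lysosome genes had one of −0.01 over 23 members, with a mean of 0.05 and a test direction that was upward (camera, adjusted p = 0.641), and it was 0.12 without control 2, 0.09 without bile acid library 1 and 0.06 without control 3. Without control 2 the member SQSTM1 passed over that list alone.

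Interferon-stimulated genes and mRNAs of the mitochondrial genome rose as lists, and both stood higher in bile acid library 1 than in any other library. The interferon list had a median log2 fold change of 0.725 over 34 members, 25 of them positive (camera, adjusted p = 0.00273, and adjusted p = 0.637 with an estimated correlation). Its level was 1.42 in bile acid library 1, against −0.11 and −0.27 in libraries 2 and 3 and −0.23, −0.31 and −0.39 in the control libraries. Without bile acid library 1 the median fell to 0.17 and the call was lost (camera, adjusted p = 0.332), as it was without control 1 (0.0742) or control 3 (0.122), while without bile acid library 3 the median was 1.09, within a range of 1.3e-07 to 0.659 over the alternatives. OAS1, an antiviral sensor of double-stranded RNA, measured 10.8 ± 14.3 CPM against 1.26 ± 0.471 CPM, with 27.3 CPM in bile acid library 1, and its log2 fold change of 3.08 fell to 1.02 without that library. The 13 mitochondrial mRNAs had a median of 0.64 and all had a positive value (camera, adjusted p = 0.00273, and adjusted p = 0.627 with an estimated correlation). Their level was 1.06 and 0.70 in bile acid libraries 1 and 3, −0.66 in bile acid library 2 and −0.83 in control 2, with 0.04 and −0.04 in controls 1 and 3. That call was lost without control 2 (median 0.33, adjusted p = 0.0565) or bile acid library 1 (0.33, adjusted p = 0.165). The median was 1.17 without bile acid library 2 and 0.41 without bile acid library 3, and the adjusted p ranged from 3.1e-09 to 0.77 over the alternatives. Adjusted over the list alone 0 members of either list passed in edgeR.

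**Figure D3:**
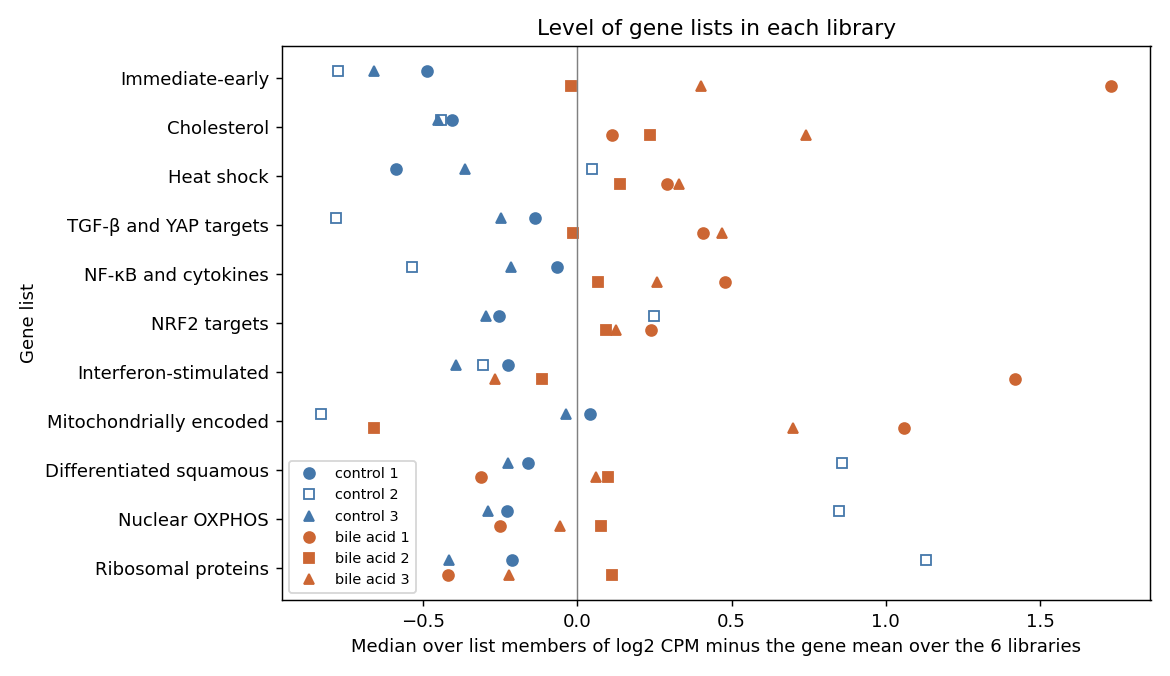
Median over the members of 11 gene lists of log2 CPM minus the gene mean over the 6 libraries (horizontal axis), with 1 point per control library (blue) and bile acid library (orange), symbols for library number and an open square for control 2. On the cholesterol list the control libraries lie between −0.45 and −0.405 and the bile acid libraries between 0.11 and 0.74, while on the ribosomal protein list control 2 lies at 1.13.

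Hypoxia and glycolysis genes rose by a median of 0.45 over 26 members, 24 of them positive (camera, adjusted p = 7.2e-06, and adjusted p = 0.510 with an estimated correlation), with the phosphofructokinase PFKP at 126 ± 54.8 CPM against 63.0 ± 28.1 CPM. The median was 0.69 without control 1, whose list level was 0.19 against −0.56 and −0.47 in controls 2 and 3. Mitosis genes rose by a median of 0.285 over 24 members, 18 of them positive (camera, adjusted p = 0.00514, and adjusted p = 0.446 with an estimated correlation), and lost the call without control 3 (adjusted p = 0.0787) or bile acid library 3 (adjusted p = 0.0592), within a range of 0.000541 to 0.535. The proliferation marker MKI67 measured 515 ± 89.6 CPM against 482.5 ± 149 CPM, and its log2 fold change of 0.09 was −0.13 without control 2 and −0.05 with the length and GC trend removed. DNA replication genes had a median of 0.06 over 23 members (camera, adjusted p = 0.55), which was −0.06 without control 1 (adjusted p = 0.832), and they rose without control 2 (0.135, adjusted p = 0.00789, the lowest of the alternatives, which reached 0.832). Genes of the BMP, Hedgehog, WNT and NOTCH pathways rose by a median of 0.36 over 27 members (camera, adjusted p = 0.00249, and adjusted p = 0.510 with an estimated correlation). Their median was −0.56 in control 2 against 0.01 and 0.02 in controls 1 and 3, and without control 2 it fell to 0.135 and the call was lost (adjusted p = 0.057, within 0.00089 to 0.535). DKK1, a secreted WNT inhibitor, measured 15.9 ± 4.01 CPM against 5.705 ± 0.79 CPM and was the only member of these 4 lists to pass in edgeR adjusted over the list alone with all libraries, joined by HES1 without control 2.

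Of the markers of epithelial identity, 10 of 16 basal squamous, 11 of 27 differentiated squamous and 12 of 34 columnar members were tested. TP63, KRT5, KRT14, KRT4, KRT13, IVL, CDX2 and MUC2 were among those with too few counts. The lists therefore cannot tell whether these identities held. Their tested members showed no shift that passed the test. Mesenchymal genes rose by a median log2 fold change of 0.27 over 23 members (camera, adjusted p = 0.000177, and adjusted p = 0.510 with an estimated correlation). Their median was −0.63 in control 2 against 0.08 and −0.10 in controls 1 and 3, so the fold change was 0.09 without control 2 (adjusted p = 0.0343), 0.57 without control 1 and 0.43 without bile acid library 2, with adjusted p between 2.1e-05 and 0.546 over the alternatives. VIM, the intermediate filament of mesenchymal cells, measured 197 ± 20.8 CPM against 146 ± 43.0 CPM, and CDH1, the epithelial cadherin, 13.4 ± 6.89 CPM against 10.6 ± 5.88 CPM. The log2 fold change of CDH1 was 0.33 and turned to −0.14 without bile acid library 1. Columnar and intestinal-type markers, looked for because Barrett metaplasia replaces squamous with columnar epithelium, had a median of 0.28 over 12 tested members (camera, adjusted p = 0.149). They rose without control 2 (0.47, adjusted p = 0.0148) or bile acid library 2 (0.36, adjusted p = 0.0446), within 0.0148 to 0.605, and 4 members then passed over the list alone without control 2, the keratins KRT18, KRT8 and KRT7 with FOXA1. Over all alternatives the median of the columnar list lay between 0.226 and 0.586. KRT8 measured 535 ± 43.0 CPM against 460 ± 172 CPM. CDX2, the intestinal master factor, had 1 count in control 3 and 1 in bile acid library 2 and 0 elsewhere. TP63, the basal squamous factor, had 2 counts in bile acid library 2 and 0 elsewhere, and the basal keratin KRT5 had 1, 0 and 12 counts in the control libraries and 4, 1 and 6 in the bile acid libraries, so neither could be compared at this depth. Basal squamous markers had a median of −0.03 over 10 members (camera, adjusted p = 0.635), between −0.21 without control 2 and 0.08 without control 3. Differentiated squamous markers had one of −0.335 over 11 members (camera, adjusted p = 0.154), with 0.86 in control 2 against −0.16 and −0.22 in controls 1 and 3. Their value was −0.01 without control 2 and −0.51 without control 3, where they fell (adjusted p = 0.0427, the lowest of the alternatives, which reached 0.961). Junction and adhesion genes had a median of 0.18 over 25 members (camera, adjusted p = 0.242). It was 0.47 without control 1 (adjusted p = 0.0521, the lowest of the alternatives, which reached 0.999), 0.34 without bile acid library 2, 0.07 without control 2 and 0.05 without bile acid library 1. Matrix proteases with their inhibitors had a median of 0.09 over 16 members (camera, adjusted p = 0.2), and 0.145 without bile acid library 1. Adjusted over the list alone 0 members of these 6 lists passed in edgeR with all libraries, and without control 2 the mesenchymal members VIM, SNAI2 and ACTA2 did, as did TIMP1 and PLAUR among the matrix protease members.

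Receptors, transporters and enzymes of bile acids had a median log2 fold change of 0.02 over 17 tested members (camera, adjusted p = 0.837), between −0.08 without bile acid library 2 and 0.31 without control 3. The bile acid receptor NR1H4, also called FXR, had 1 count in bile acid library 3 and 0 in the other libraries, where the floor of 3 counts lies at 0.105 to 0.143 CPM. GPBAR1, the membrane receptor TGR5, had 3, 4 and 4 counts in the control libraries and 10, 14 and 13 in the bile acid libraries, below the filter for testing. VDR, which also binds lithocholic acid, measured 10.1 ± 1.27 CPM against 8.445 ± 2.43 CPM, a difference within the spread between libraries (edgeR, adjusted p = 0.911). Acid-sensing and pH-regulating genes had a median of 0.18 over 21 members (camera, adjusted p = 0.109), and 0.31 without control 3. Markers of other cell types did not move as lists. Fibroblast markers had a median of −0.01 over 9 members with a mean of 0.25 and a downward test direction (camera, adjusted p = 0.951), and leukocyte markers one of 0.20 over 7 members (camera, adjusted p = 0.951). Endothelial markers had a median of 0.01 over 7 members with a downward test direction (camera, adjusted p = 0.75), and epithelial markers of columnar cancer lines one of 0.02 over 12 members with a downward test direction (camera, adjusted p = 0.951). The last list rose without control 2 (0.12, adjusted p = 0.0413, the lowest of the alternatives, which reached 0.977), with KRT18 and KRT8 passing over the list alone, genes that the columnar list also holds. With 1 library left out the medians lay between −0.07 (control 3) and 0.19 (control 1) for fibroblast, −0.15 (control 2) and 0.35 (bile acid library 3) for leukocyte and −0.39 (control 2) and 0.24 (bile acid library 1) for endothelial markers, and the cancer line markers reached −0.09 without bile acid library 1. Adjusted over the list alone 0 members of these 6 lists passed in edgeR with all libraries.

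Ribosomal protein genes were the 1 list that fell, by a median of 0.36 on the log2 scale over 26 members, all with a negative value (camera, adjusted p = 0.00081, and adjusted p = 0.677 with an estimated correlation). RPS12 measured 668 ± 186 CPM in bile acid libraries against 1321 ± 1180 CPM in control libraries, with 2684 CPM in control 2. The list level was 1.13 in control 2, against −0.21 and −0.415 in controls 1 and 3 and −0.42, 0.11 and −0.22 in bile acid libraries 1 to 3. Without control 2 the direction turned and the list median was 0.11 (camera, adjusted p = 0.0423, and 0.77 with an estimated correlation), with the levels of the groups overlapping. The median was −0.55 without control 1 and −0.64 without control 3, and the adjusted p ranged from 1.1e-06 to 0.77 over the alternatives. The log2 fold changes of RPS12, RPLP2 and RPL32 were −0.98, −0.92 and −0.74 with all libraries and 0.07, 0.19 and 0.09 without control 2. Ribosomal protein genes have many processed pseudogenes, so their single values are uncertain. Nuclear genes of oxidative phosphorylation had a median of −0.18 over 28 members (camera, adjusted p = 0.264) and a level of 0.85 in control 2 against −0.23 and −0.29 in controls 1 and 3. They rose without control 2 (0.22, adjusted p = 9.5e-05) and fell without control 1 (−0.38, adjusted p = 0.0209) or control 3 (−0.36, adjusted p = 0.0197), with a highest adjusted p of 0.871. Replication-dependent histone genes had a median of −0.295 over 11 members (camera, adjusted p = 0.316) and fell without control 3 (−0.69, adjusted p = 0.0304, the lowest of the alternatives, which reached 0.784), while their median was 0.05 without control 1 and −0.09 without control 2.

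More genes passed when control 2 was left out or given little weight. DESeq2 without it called 158 of 16146 genes with an adjusted p, 143 higher and 15 lower, and limma-voom with quality weights on all 6 libraries, which gave control 2 a weight of 0.0801, called 148, 119 higher and 29 lower, with 106 genes in both. The weights were 2.54 and 1.65 in controls 1 and 3 and 0.916, 0.811 and 4.00 in bile acid libraries 1 to 3. The weighted fit thus leaned on bile acid library 3. Since control 2 was left out of 1 fit and given little weight in the other, the shared genes are not independent agreement. Under an unadjusted p of 0.05 DESeq2 without control 2 had 1424 genes, where chance gives 807. The fit with quality weights had 2938, where chance gives 887. edgeR without control 2 called 1 gene of 18274, with 1459 under an unadjusted p of 0.05, where chance gives 914. That gene, singled out after its value was seen, was MT2A, a metallothionein that binds zinc and copper (chromosome 16, 56608199 to 56609497, plus strand), with a log2 fold change of 2.12 (SE 0.23, edgeR adjusted p = 0.0436). MT2A measured 174 CPM, 1009 CPM and 221 CPM in control libraries 1 to 3 and 1012 CPM, 608 CPM and 931 CPM in bile acid libraries 1 to 3, so that with control 2 its log2 fold change was 0.86 (SE 0.65, edgeR adjusted p = 0.911), and its adjusted p ranged from 3.1e-17 to 1 over 26 alternatives. Metallothioneins are near-identical family members, so reads can be shared between them and the value of a single member is uncertain.

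The authors' deposited table of the same comparison lists 22164 genes, 14713 of them with an adjusted p, and calls 19, all higher in bile acid libraries and all with a log2 fold change of at least 1. FOS leads the authors' deposited table with a log2 fold change of 3.34 (DESeq2, adjusted p = 4.4e-05), followed by HSPA6 with 3.095 (adjusted p = 0.000192), EGR1 with 3.465 (adjusted p = 0.000202) and HMGCS1 with 1.80 (adjusted p = 0.000978). Other genes called in the authors' deposited table include TMEM156, JUNB, INSIG1, DKK1, IKBKGP1, DUSP1, ZFP36, FDFT1, MYC, IER3, DUSP6, TM4SF1 and HAS2. Of these 19 genes 16 were also called by DESeq2 on the count table, and 19 of 19 had a positive value in edgeR. The sign was the same in edgeR and in the authors' deposited table for 96.9% of the 15589 genes in both.

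The authors' deposited table of gene sets names 2196 Gene Ontology terms, 2114 with a positive and 82 with a negative normalized enrichment score. Its highest score was that of miRNA transcription, 2.70, and cholesterol biosynthetic process scored 2.60 (adjusted p = 2.3e-08 in the authors' deposited table). Low scores included mitochondrial respiratory chain complex assembly with −2.76 (adjusted p = 5.1e-09 in the authors' deposited table), mitochondrial translation with −2.47, cytochrome complex assembly with −2.35 and cytoplasmic translation with −2.33. In the edgeR fit the leading-edge genes of all 82 negative terms had a median log2 fold change below 0 with all libraries and without control 1 or control 3, and those of 36 terms without control 2. Without control 2 the median for cytoplasmic translation was 0.13, against −0.545 with all libraries, and that for cytochrome complex assembly −0.02, against −0.63. The leading-edge genes of 2113 of the 2114 positive terms kept a median above 0 without control 2. That count decides little, since these genes were picked for being high in these same libraries, most of which remain.

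In the deposited FPKM values, which scale counts by gene length as well as depth, HMGCS1 measured 33.4 ± 11.2 FPKM in bile acid libraries against 9.78 ± 2.56 FPKM in control libraries, INSIG1 167 ± 38.4 FPKM against 69.8 ± 6.92 FPKM and FOS 50.0 ± 41.5 FPKM against 5.10 ± 1.67 FPKM (mean ± SD, n = 3). MT2A measured 558 ± 140 FPKM against 309 ± 305 FPKM and RPS12 743 ± 207 FPKM against 1480 ± 1300 FPKM. Tested with limma on log2(FPKM + 1), 0 genes were called with or without a minimum mean of 0.5. With it 474 of 15042 genes had an unadjusted p under 0.05, where chance gives 752. Without it 916 of 31022 did, where chance gives 1551. The FPKM of each library were 0.817 to 0.846 of the value that its count total and the gene length give, except in control 2, where the ratio was 1.001.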

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

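The fits that leave out control 2 with DESeq2 or with an estimated correlation, those with quality weights, those on recovered reads and camera with the length and GC trend removed were chosen after control 2 was seen to stand apart. The count of called genes, 0 in edgeR, was 0 in 15 other planned fits on all 6 libraries, and 19 with DESeq2, 158 with DESeq2 without control 2, 148 with quality weights and 19 with DESeq2 on recovered reads, and 0 to 1 with each library left out. The 1 gene was called by edgeR without control 2, and 16 of the 158 genes were also called by DESeq2 with all libraries. Why these counts differ between tools and libraries was not tested. The count of called lists, 15, fell to 0 with an estimated correlation, 0 with fry and 0 with an estimated correlation without control 2, and stayed between 12 and 19 with each library left out. The camera fit with an estimated correlation on all libraries differs from the main one in that setting alone, so the calls ended because of it. The correlation was estimated at 0.178 for the cholesterol list, 0.629 for the immediate-early list and 0.979 for ribosomal proteins, against the preset 0.01. Why list members vary together was not tested. With the replicate block 0 genes were called, with 1109 under an unadjusted p of 0.05 against 588 without it, where chance gives 887. With that block 15 lists were called. The ATF4 list was newly called lower (−0.22, camera, adjusted p = 0.00791) and the apoptosis list lost its call (0.16, camera, adjusted p = 0.121). Deviations of same-numbered libraries correlated at 0.307, 0.382 and 0.0979. Control 3 correlated best with bile acid library 1 and bile acid library 3 with control 1, so not every library correlated best with its own number. Libraries 1 and 2 of each group did, and both libraries numbered 2 fell with gene length (rho of −0.501 and −0.474). Deviations from a mean of 3 libraries depend on each other, so they cannot decide whether a number marks a shared batch. Over the named genes and all their alternatives, 1866 values kept their direction and side of the threshold, 106 gained a call and 16 turned their direction, and over the lists 370 kept both, 59 lost a call, 15 gained one and 32 turned, where a direction is that of the test. Without control 2 and with an estimated correlation the turned lists were differentiated squamous (−0.00655), nuclear oxidative phosphorylation (0.217), ribosomal proteins (0.113), fibroblast (0.0171), leukocyte (−0.153) and columnar cancer line markers (0.124). With fry and with the block the fibroblast (−0.0141) and cancer line lists (0.0227) turned, as did the latter with genes of 1 list alone (0.0443) and with the trend removed (0.0421), and the leukocyte list with the CPM filter (−0.195). With each library left out the list medians ranged over −0.0612 to 0.135 (DNA replication), −0.206 to 0.0841 (basal squamous), −0.506 to −0.00655 (differentiated squamous), −0.0818 to 0.314 (bile acid handling), −0.383 to 0.217 (nuclear oxidative phosphorylation), −0.032 to 0.119 (autophagy), −0.642 to 0.113 (ribosomal proteins), −0.0664 to 0.187 (fibroblast), −0.153 to 0.353 (leukocyte), −0.392 to 0.241 (endothelial) and −0.0886 to 0.124 (cancer line markers). MKI67 was −0.0527 with the trend removed, −0.056 with the block added, −0.132 in DESeq2 without control 2 and −0.0425 with quality weights, and CDH1 was −0.0947 with quality weights. In DESeq2 without control 2 RPS12 was 0.0736, RPLP2 0.188 and RPL32 0.0913, and RPLP2 was 0.036 with quality weights. With each library left out the log2 fold changes ranged over −0.117 to 2.51 for PTGS2, −0.139 to 0.623 for HMOX1, −0.131 to 0.271 for MKI67, −0.144 to 0.89 for CDH1, −1.33 to 0.0747 for RPS12, −1.27 to 0.189 for RPLP2 and −1.04 to 0.0924 for RPL32. For the turned values that do not come from leaving out control 2 the cause was not tested. Depth limits genes near or below 0.105 to 0.143 CPM, such as NR1H4.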

Other observations

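The tests of gene length, of control 2 having been handled apart and of the cholesterol list without control 2 or without the length trend and of the ribosomal protein list without that trend were chosen after the results were seen, as were the metallothioneins, ID1, DDR2, ANK2, NBPF1 and HSPA1A as genes to name. The metallothioneins MT2A, MT1E and MT1X were not called with all libraries (edgeR, adjusted p = 0.911 for each). MT1E measured 65.5 CPM, 151 CPM and 61.1 CPM in control libraries 1 to 3 and 257.5 CPM, 139.5 CPM and 237 CPM in bile acid libraries 1 to 3, and without control 2 its log2 fold change was 1.75 (SE 0.24) where it was 1.19 with all libraries. MT1X went the same way, with 1.38 (SE 0.28) without control 2 and 0.73 with it, and both are uncertain as single genes because the family is near-identical. ID1, an inhibitor of differentiation factors and a BMP target, measured 46.5 CPM, 128 CPM and 49.8 CPM in the control libraries and 105 CPM, 152 CPM and 178 CPM in the bile acid libraries. Its log2 fold change was 1.60 (SE 0.21) without control 2 and 0.96 with all libraries (edgeR, adjusted p = 0.911). In DESeq2 without control 2 the adjusted p was 1.4e-09 for MT1E and for ID1 and 0.000712 for MT1X, and over the 26 alternatives of each gene it reached 1.

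The 15 genes that DESeq2 called lower without control 2 included DDR2, a collagen receptor, and ANK2, an ankyrin that anchors membrane proteins to the cytoskeleton. In edgeR without control 2 DDR2 had a log2 fold change of −0.85 (SE 0.17) and ANK2 one of −1.15 (SE 0.24). NBPF1, with −0.71, belongs to a family of near-identical copies and is uncertain. With all libraries their log2 fold changes were −0.58, −0.97 and −0.36 (edgeR, adjusted p = 0.911 for each). DESeq2 without control 2 gave adjusted p of 0.00432, 0.00433 and 0.00103, the lowest among the alternatives, which reached 1. HSPA1A, with 57.8 ± 31.2 CPM in control libraries and 93.9 ± 15.4 CPM in bile acid libraries, had a log2 fold change of 0.70 with all libraries and 1.24 without control 2.

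Control 2 differed from controls 1 and 3 with an SD of 0.961 in log2 difference over 12077 genes. A swap of its label with a bile acid library is argued against, since the lowest bile acid library lay 0.552 above control 2 on the cholesterol list and no bile acid library lay at the level of the controls. Gene length is likely part of the difference, with a rho of −0.501. The trend with annotated exonic length is not the whole of it, since the SD stayed at 0.846 once that trend was removed. Its FPKM were 1.001 of the value its count total gives and those of the other 5 were 0.817 to 0.846. That ratio cannot decide whether the library was prepared, sequenced or processed apart from the others. It was higher where the TMM factor was lower, with factors of 0.851 in control 2 and 1.01 to 1.069 in the others. Scaling by such a factor could give the ratio without separate handling. Whether any step differed stays open, and no biological explanation was tested, as the design gives none within a group.

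The 82 negative Gene Ontology terms in the deposited table, led by mitochondrial assembly and translation, may come from control 2 alone. Without it 43.9% of them kept a leading-edge median below 0, while all did without control 1 or control 3. For ribosomal protein genes, a list fixed beforehand, the median was −0.295 with the length and GC trend removed and −0.358 before (camera, adjusted p = 0.00167 and 0.00081, and 1.1e-06 to 0.77 over all alternatives). This does not decide whether the trend is the whole cause. The lengths used count all annotated exons, 3720 bp for RPL32, and the expressed transcript can be shorter. The estimated correlation between members was 0.979. For the terms as a set the trend as the whole cause also stays open. That 100% of them kept a median below 0 with the trend removed decides nothing, although that bound was set beforehand, because leading-edge genes were picked for being low in these libraries. A fall of ribosomal protein genes under bile acids was seen only with control 2 included. Without control 2, 25 of the 26 members had a positive value, so no fall is seen there. The ribosomal protein median was then 0.11 (camera, adjusted p = 0.0423, and 0.77 with an estimated correlation). The list levels of the groups overlapped, so a small change either way stays undecided.

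The rise of the cholesterol and immediate-early lists is not explained by control 2 alone, since without it the cholesterol median was 0.718 and the immediate-early median 1.36. The length and GC trend is argued against as well, with medians of 0.827 and 1.42 once it was removed. Handling at harvest, which can set off immediate-early genes within minutes, could have raised the immediate-early list in single wells, as its median spans 1.75 between the 3 bile acid libraries and that of the cholesterol list 0.631. No control library reached a bile acid library on the immediate-early list, and harvest and exposure cannot be told apart for these genes because the labels give no handling record. A response to bile acids or to acid remains among the open explanations for both lists, untested against each other.

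The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. All 10 splits gave as many called genes in edgeR as the real one, with 0 in the real split and 0 as the highest other. Counts of 0 throughout cannot tell the real split from the others. Under an unadjusted p of 0.05 the real split had 588 genes. Other splits had more, with 698, 1012 and 1327, and the rest had fewer, down to 83. For lists 2 of the 10 splits gave at least as many calls, the real one with 15 and 1 other, controls 1 and 3 with bile acid library 2 against the rest, with 16.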
